A study of Rattus norvegicus with 38 samples.

How the data were processed

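RNA of blood leukocytes from male Fischer rats was measured on 38 single-channel Applied Biosystems rat genome arrays, 1 array per rat. Per the labels, leukocytes were caught on a filter, total RNA was depleted of globin mRNA, and digoxygenin-labelled cRNA was detected by chemiluminescence. The deposited signal of each array is a linear intensity per probe, from which a background had been subtracted and which had not been scaled between arrays. The deposited signal-to-noise ratio is a score per probe, as the scanner software gives it. The authors also deposited whole-number quality flags per spot, a column of other kind without a measurement unit. The series table of the authors holds log2 values, which equalled the log2 of the quantile-normalized signals to within 5e-09. Scanner settings, slides and scan dates are not given, so that no batch could be tested, and the genome build of the array is not stated, so that no coordinates are given.

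The 10 groups were the vehicle rats of each chemical and the rats killed 4, 12, 24 and 168 h after dosing. Signals of 26857 gene probes were quantile-normalized over the 38 arrays, raised to a floor at the 5th percentile (a signal of 84.7) and put on the log2 scale, and spots with a flag of 5000 or more were set missing (0.9598% of values). Probes were tested where the signal-to-noise ratio was at least 3 in the majority of arrays of at least 1 group and each group kept at least 2 values, which left 12805 of the 12807 detected probes. Exactly 1 gene symbol was known for 6104 probes, several for 70 and none for 20683, so that 3442 genes were tested by name through 3499 probes. Of these genes 52 had more than 1 tested probe, and 1 gene had probes called both ways in 1 comparison, 168 h after acetaminophen. The 322 control spots were not part of the comparisons. Array signal gives no count of molecules, and the number of arrays limits the precision.

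A linear model with 1 factor of 10 groups was fitted with limma 3.58.1 in R 4.3.3, with a variance prior that follows the mean signal (28 residual and 6.31 prior degrees of freedom). Each treated group was compared with the vehicle rats of its chemical, the 2 chemicals were compared with each other at each time as a difference of these changes, and the vehicle groups were compared with each other. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over the 12805 probes with a threshold of 0.05. Whole gene lists were tested with limma's camera, which compares the members with all other named genes, with a preset correlation of 0.01. Its p was adjusted over 31 lists and 8 comparisons (248 tests), and over 124 tests for the differences. Members that rose or fell are given over all genes and adjusted over the list alone. Some lists share members, such as Il1r2 in the neutrophil and the glucocorticoid-induced list, so that their calls are not independent. With a correlation estimated from the arrays none of the 58 called pairs of list and comparison passed, nor any of the 37 called differences, and the smallest adjusted p was 0.29. Values of flagged spots were used as measured in camera, which takes no missing values. List members were matched by current symbol, by the array's symbol or by a former symbol. At first a former symbol also matched where that name is the current symbol of another gene, and this was corrected after the results had been seen. The correction dropped 5 tested places in the lists, and 56 pairs and 35 differences were called before it. B cell markers 24 h after acetaminophen had an adjusted p of 0.206 before and 0.0211 after it, and cell cycle genes 4 h after methyl parathion 0.0504 and 0.0495. The differences gained were those of B cell markers at 24 h (0.244 before, 0.0345 after) and heart muscle genes at 168 h (0.112 before, 0.00453 after).

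The groups, comparisons, filters, lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 probes with the largest rise and the 10 with the largest fall among probes with 1 symbol that passed the test and whose treated arrays all lay beyond all control arrays. It also took the 4 members with the smallest p and the largest contrary member of each called list, the 6 largest differences between the chemicals each way, and Ache, Bche and Hmox1 in every group. Probes with no array of a group above the signal-to-noise limit are given as lower bounds of the fold, and no fold is given where both groups were below it. Where only 1 treated array was above the limit, a change with its SE is given and is less certain. Examples are Srms at 4 h, Hdc and Thrb at 12 h, and Hspa14 and Thy1 at 168 h after acetaminophen. Others are Sv2b at 12 h, Mag, Mdm4 and Clmp at 24 h, and Gja4 at 168 h after methyl parathion. Rat numbers within a group are labels: deviations from group means correlated at -0.4 to 0.21 between arrays of the same number in treated and vehicle groups, so that no pairing was used. Alternatives were median centring in place of quantile normalization, the series table, no filter or a stricter one, a floor at the 25th percentile, flagged spots kept, all 8 vehicle rats pooled, array weights, only the groups compared, no trend of the variance prior, calls of at least 2-fold, a replicate block, and leaving out each rat in turn. Array brightness and the ratio of kit control spots to gene probes were added as covariates after the data had been seen. A correction of foreground and background was not run, since the files hold neither column.

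The steps were checked on simulated data with 100 probes changed 2-fold and 100 changed 4-fold per comparison. From 41 to 48% of the 2-fold and 75 to 82% of the 4-fold changes were recovered, none in the wrong direction. False calls were 0.769 to 7.35% of calls, above 5% at 24 and 168 h after acetaminophen (7.35 and 5.43%) and 4 h after methyl parathion (6.87%). A shift of -0.5 log2 put on the T cell markers gave an adjusted p of 1.1e-08, or 2.5e-05 with an estimated correlation, and 0 other lists were called. Noise was drawn independently for each probe, so that members of a list did not vary together. The simulation therefore cannot show how either form of the list test behaves on genes that are expressed together. The figures were drawn with matplotlib 3.10.9.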

Results

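Blood leukocyte RNA was profiled in rats given 1200 mg/kg acetaminophen, an analgesic that injures the liver at high dose, or 15 mg/kg methyl parathion, an organophosphate insecticide that inhibits acetylcholinesterase. Both were injected intraperitoneally in vegetable oil. The question was whether blood transcripts carry signs of toxicity in a target organ and tell the chemicals apart. Groups held 4 rats at 4, 12 and 24 h and 3 at 168 h, and each chemical had 4 vehicle rats, all killed at 24 h. The hour of killing is therefore not matched at 4 and 12 h. No vehicle rat was kept to 168 h, so that age and handling are not matched there. Median raw signal ran from 176.6 to 389.6 over the arrays, and 36.41 to 51.7% of probes were above background. Arrays of a group correlated at 0.9156 to 0.9828 across probes.

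The first principal component held 24.63% of the variance and the second 11.91%. Over 38 arrays, the only relation of this kind computed, raw median signal was related to the second component (Pearson's r = 0.546, permutation p = 0.00043; Spearman's rho = 0.545, permutation p = 0.00058; r = 0.582 without the 2 arrays farthest from the median signal, and r = 0.623 for deviations from group means). Labelling kit control spots, relative to gene probes, were at 7.1 ± 0.186 log2 in the acetaminophen vehicle rats and 7.07 ± 0.281 in those of methyl parathion (SD, n = 4 each). They were at 7.5 ± 0.26 (n = 3) at 168 h after acetaminophen, and at 7.4 ± 0.195, 7.47 ± 0.366, 7.44 ± 0.229 and 7.64 ± 0.532 at 4, 12, 24 and 168 h after methyl parathion (SD). For these 5 differences exact permutation p was 0.0857 to 0.171 (adjusted p = 0.18 to 0.23 over 8 groups), with groups too small for a single difference to pass, so that this does not show that the ratio was alike.

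**Figure D1:**
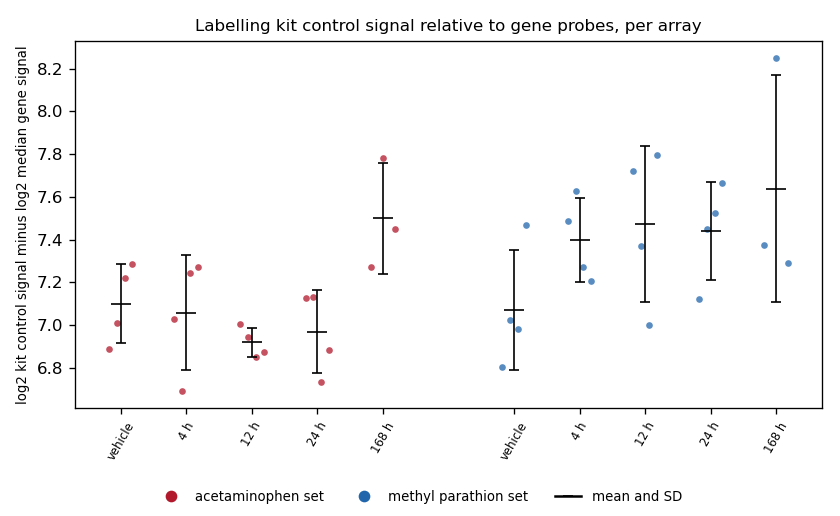
Mean log2 signal of the labelling kit control spots minus log2 median signal of gene probes on each array (y axis), by group (x axis); points are arrays, bars the mean and SD. The acetaminophen 168 h mean is 7.5 and the methyl parathion 168 h mean 7.64, against 7.1 and 7.07 in the vehicle groups.

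At 4 h after acetaminophen, B cell and T cell transcripts were lower, and platelet and glucocorticoid-induced transcripts higher, than in the vehicle rats (n = 4 and 4). Log2 changes were -2.98 ± 0.507 (SE) for Ebf1, a transcription factor of B cell development, -2.72 ± 0.619 for Fcer2, the low-affinity IgE receptor, and -2.44 ± 0.375 for Cd79b, a chain of the B cell receptor. Crispld2, a secreted protein induced by glucocorticoids, rose by 3.17 ± 0.835, and Il1r2, a decoy receptor of interleukin 1, by 2.71 ± 0.525. Of 6 B cell markers 4 fell (5 adjusted over the list alone; mean -1.65, camera adjusted p = 3.74e-05, and adjusted p = 0.41 with an estimated correlation). Rat 1 stood apart, with a B cell score of -0.26 log2 from the vehicle mean, beside a lowest vehicle score of -0.19, against -1.77 to -2.43 in the other 3. Of 16 T cell markers 7 fell (9 adjusted over the list alone; mean -0.66, adjusted p = 1.66e-05, and adjusted p = 0.51 with an estimated correlation). Changes included Cd3d by -1.05 ± 0.232, a chain of the T cell receptor complex, and Lat by -0.94 ± 0.198, its signalling adaptor. Of 12 platelet genes 6 rose (9 rose and 1 fell adjusted over the list alone; mean 1.04, adjusted p = 9.47e-05, and adjusted p = 0.41 with an estimated correlation). The platelet score was above all vehicle rats in 3 of 4. Rises included Ltbp1 at 1.95 ± 0.412, Gp5, a von Willebrand factor receptor subunit, at 1.93 ± 0.463, and Ppbp, a platelet chemokine, at 1.60 ± 0.384. Of 15 glucocorticoid-induced genes 4 rose (7 adjusted over the list alone; mean 0.85, adjusted p = 3.76e-05, and adjusted p = 0.41 with an estimated correlation). Changes included Fkbp5, a co-chaperone of the glucocorticoid receptor, at 1.80 ± 0.409 and Klf9 at 0.70 ± 0.216.

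Of 10 MHC class II genes 3 fell at 4 h (6 adjusted over the list alone; adjusted p = 0.00341, and adjusted p = 0.58 with an estimated correlation). Their score was below all vehicle rats in 3 of 4, and RT1-DOa changed by -1.49 ± 0.307. Erythroid genes were higher as a list, with 2 of 15 past the test (3 adjusted over the list alone; adjusted p = 0.00594, and adjusted p = 0.66 with an estimated correlation). These were Nfe2 at 1.09 ± 0.236 and Rhag at 1.42 ± 0.415, and the score was above all vehicle rats in 2 of 4. Of 37 ribosomal protein genes 1 fell (0 adjusted over the list alone; mean -0.29, adjusted p = 2.94e-07, and adjusted p = 0.56 with an estimated correlation). Of 34 oxidative phosphorylation genes 3 fell (14 fell and 2 rose adjusted over the list alone; adjusted p = 3.74e-05, and adjusted p = 0.56 with an estimated correlation). Of 26 proteasome genes 3 fell (6 adjusted over the list alone; adjusted p = 0.000513, and adjusted p = 0.59 with an estimated correlation). Smaller shifts upward were seen for natural killer genes (1 of 17 rose and 1 fell; 3 and 1 adjusted over the list alone; adjusted p = 0.0443, and adjusted p = 0.86 with an estimated correlation) and hepatocyte genes (0 of 21, and 2 adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.58 with an estimated correlation). They were also seen for endoplasmic reticulum stress genes (2 of 23, and 3 adjusted over the list alone; adjusted p = 0.0186, and adjusted p = 0.56 with an estimated correlation) and hypoxia and glycolysis genes (3 of 32, and 4 adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.56 with an estimated correlation). The natural killer and hypoxia scores were above all vehicle rats in 3 of 4. Within these lists, Klrg1 rose by 1.07 ± 0.266, Ncr3 changed by -1.45 ± 0.436, Ddit3 rose by 0.94 ± 0.187 and Gapdh by 0.97 ± 0.195.

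In all, 842 of 12805 probes passed the limma test at 4 h after acetaminophen (371 higher, 471 lower; 259 named genes). Other large changes were rises of Tyro3, a receptor tyrosine kinase, at 2.04 ± 0.437, Pir at 2.01 ± 0.525, Galnt14 at 1.97 ± 0.424 and Angpt1 at 1.91 ± 0.443. Syt5 was at least 4.58-fold and Tgm1 (3 vehicle values) at least 4.28-fold higher. Falls were seen for Ell3 at -2.03 ± 0.337, Hpgds, the prostaglandin D synthase of mast cells, at -2.03 ± 0.391, Srms at -1.96 ± 0.421, Tmbim1 at -1.80 ± 0.329 and Rnase6 at -1.65 ± 0.443. Fcer1a, a chain of the high-affinity IgE receptor, was at least 3.31-fold lower. The count fell to 0 when limma saw only these 8 arrays and to 201 with median centring. Median centring sets the median of all gene probes alike, and the median change of the tested probes was -0.11 with it (-0.031 with quantile normalization). The count was 540 with no detection filter and 2365 with array weights. It was 179, 360 and 420 without rats 3, 2 and 4 of the 4 h group, 1624 without rat 1, and 539 and 389 without vehicle rats 1 and 4.

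At 12 h after acetaminophen, neutrophil and inflammatory transcripts were higher and T cell transcripts lower (n = 4 and 4). Crispld2 rose by 6.49 ± 0.835, Ltb4r, the leukotriene B4 receptor, by 5.11 ± 0.523 and Il1r2 by 5.06 ± 0.525 log2. Tgm1, a transglutaminase, was at least 48.4-fold and Alpl, the tissue-nonspecific alkaline phosphatase, at least 28.8-fold higher. Socs3, an inhibitor of cytokine signalling, rose by 4.39 ± 0.405, Hp, haptoglobin, by 4.38 ± 0.345, Dgat2 by 4.36 ± 0.388 and Dusp4 by 4.15 ± 0.477. Ifit1, an interferon-induced gene, was at least 20.5-fold higher. Of 12 neutrophil markers 9 rose and 2 fell, also adjusted over the list alone (mean 1.76, adjusted p = 0.000716, and adjusted p = 0.56 with an estimated correlation). The rises included Mmp8, the neutrophil collagenase, at 4.14 ± 0.39, Cxcr2, a chemokine receptor, at 3.88 ± 0.459 and Mmp9 at 3.10 ± 0.277. Fcgr3a changed by -1.54 ± 0.304. Of 16 T cell markers 15 fell, also adjusted over the list alone (mean -1.53, adjusted p = 2.94e-07, and adjusted p = 0.41 with an estimated correlation). Changes included Cd3d at -2.11 ± 0.232, Lat at -1.87 ± 0.198 and Cd5 at -1.86 ± 0.245. Some cell type lists not called here also moved in every rat. B cell, MHC class II and eosinophil scores were below all vehicle rats in 4 of 4 (means -0.978, -0.667 and -0.839). Platelet and monocyte scores were above them in 4 of 4 (means 0.897 and 0.519).

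Of 15 glucocorticoid-induced genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.000406, and adjusted p = 0.51 with an estimated correlation). Anxa1 rose by 3.39 ± 0.285, Cebpd by 2.85 ± 0.25 and Dusp1 by 2.84 ± 0.31. Of 19 inflammatory cytokine and NF-kB target genes 9 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00178, and adjusted p = 0.41 with an estimated correlation). Changes included Il1rap at 3.35 ± 0.37 and Tlr2, a receptor of bacterial lipoproteins, at 2.45 ± 0.217. Of 19 immediate early genes 10 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 0.00788, and adjusted p = 0.44 with an estimated correlation). Ier3 rose by 2.67 ± 0.233, while Myc changed by -1.39 ± 0.182. Of 32 hypoxia and glycolysis genes 15 rose and 3 fell (16 and 4 adjusted over the list alone; adjusted p = 0.00158, and adjusted p = 0.49 with an estimated correlation). Changes included Hk3, a hexokinase, at 3.50 ± 0.471. Ribosomal protein genes fell in 33 of 37 cases, also adjusted over the list alone (mean -0.79, adjusted p = 2.68e-14, and adjusted p = 0.41 with an estimated correlation). Oxidative phosphorylation genes fell in 29 of 34, also adjusted over the list alone (mean -0.59, adjusted p = 7.81e-08, and adjusted p = 0.41 with an estimated correlation). Changes included Rpl3 at -1.29 ± 0.158 and Atp5f1e at -1.47 ± 0.173. Of 26 proteasome genes 12 fell, also adjusted over the list alone (adjusted p = 0.0128, and adjusted p = 0.72 with an estimated correlation). Of 12 heat shock genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.0128, and adjusted p = 0.58 with an estimated correlation). Hspe1, a mitochondrial chaperonin, changed by -1.28 ± 0.15.

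A total of 4389 probes differed at 12 h after acetaminophen (1769 higher, 2620 lower; 1402 named genes). Large falls were those of Hdc, which makes histamine, at -3.88 ± 0.638, Rnase6 at -3.72 ± 0.443, Tgm2, a transglutaminase, at -2.89 ± 0.301, Eno3 at -2.61 ± 0.332, Thrb, a thyroid hormone receptor, at -2.47 ± 0.763, Soat2 at -2.43 ± 0.385, St8sia1 at -2.37 ± 0.483, Cd40lg, the T cell ligand of CD40, at -2.36 ± 0.282 and Ccl9 at -2.32 ± 0.417. Dnase2b was at least 12.5-fold lower. Leaving out any 1 rat left between 3806 and 4213 probes.

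At 24 h after acetaminophen, hepatocyte and neutrophil transcripts were higher and natural killer cell transcripts lower (n = 4 and 4). Tf, transferrin, rose by 4.08 ± 0.21 and Hp by 5.48 ± 0.345 log2. Both were above background in all 4 vehicle rats, at mean log2 signals of 14.94 and 13.28 against 7.246 for Alb, and had already risen by 2.48 and 4.38 at 12 h. The name of the list therefore does not give the source of these transcripts. Alb, albumin, was at least 51.6-fold higher, and Mup5 and Mup4, major urinary proteins, were at least 68.5-fold and 58.8-fold higher. Of 21 hepatocyte genes 14 rose (16 adjusted over the list alone; mean 1.83, adjusted p = 0.000129, and adjusted p = 0.41 with an estimated correlation). Ttr, transthyretin, was at least 6.4-fold higher. Neutrophil markers rose in 9 of 12 cases and fell in 1, also adjusted over the list alone (mean 2.21, adjusted p = 1e-04, and adjusted p = 0.51 with an estimated correlation). Changes included Il1r2 at 6.34 ± 0.525, Mmp9 at 4.85 ± 0.277 and Itgam at 2.95 ± 0.254. Fcgr3a changed by -3.09 ± 0.304. Natural killer and cytotoxic cell markers fell in 16 of 17 cases (16 fell and 1 rose adjusted over the list alone; mean -1.54, adjusted p = 2.88e-08, and adjusted p = 0.49 with an estimated correlation). Changes included Nkg7 at -2.40 ± 0.208, Ccl5 at -1.93 ± 0.195 and Klrd1 at -1.77 ± 0.164. T cell markers fell in 13 of 16 (14 adjusted over the list alone; mean -1.31, adjusted p = 1.81e-05, and adjusted p = 0.51 with an estimated correlation). B cell markers fell in 5 of 6, also adjusted over the list alone (mean -1.74, adjusted p = 0.0211, and adjusted p = 0.56 with an estimated correlation). Of lists not called here, the eosinophil score was below all vehicle rats in 4 of 4 (mean -0.814). The platelet score was above them in 4 of 4 (mean 0.738).

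Car4, a membrane carbonic anhydrase, was at least 236-fold, Cxcl2, a chemokine for neutrophils, at least 110-fold, Tgm1 at least 99.9-fold and Alpl at least 63.1-fold higher at 24 h. Crispld2 rose by 6.51 ± 0.835, Ltb4r by 6.41 ± 0.523 and Ccl2, a chemokine for monocytes, by 5.75 ± 0.561. Inflammatory cytokine and NF-kB target genes rose in 12 of 19 cases and fell in 3 (13 and 3 adjusted over the list alone; mean 2, adjusted p = 7.79e-05, and adjusted p = 0.41 with an estimated correlation). Interferon-stimulated genes rose in 14 of 25 and fell in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.0051, and adjusted p = 0.7 with an estimated correlation). Changes included Oas1k at 3.40 ± 0.276 and Oas1a at 2.92 ± 0.235 but Mx1 at -1.29 ± 0.323. Nrf2 and oxidative stress genes rose in 12 of 24 and fell in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.41 with an estimated correlation). Nqo1, a quinone reductase, rose by 2.91 ± 0.208 and Txnrd1 by 2.54 ± 0.217. Endoplasmic reticulum stress genes rose in 11 of 23 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.62 with an estimated correlation). Xbp1 rose by 2.64 ± 0.195. Hypoxia and glycolysis genes rose in 18 of 32 and fell in 3 (19 and 3 adjusted over the list alone; adjusted p = 4.35e-05, and adjusted p = 0.41 with an estimated correlation). Immediate early genes rose in 10 of 19 with 4 falling (12 and 4 adjusted over the list alone; adjusted p = 0.0487, and adjusted p = 0.56 with an estimated correlation). Glucocorticoid-induced genes rose in 9 of 15 with 2 falling, also adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.66 with an estimated correlation). Ribosomal protein genes fell in 34 of 37, also adjusted over the list alone (mean -0.87, adjusted p = 5.67e-15, and adjusted p = 0.41 with an estimated correlation). Oxidative phosphorylation genes fell in 22 of 34 (25 adjusted over the list alone; mean -0.41, adjusted p = 0.000312, and adjusted p = 0.58 with an estimated correlation).

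At 24 h 4558 probes differed (1882 higher, 2676 lower; 1457 named genes). Large falls were those of Rnase6 at -4.34 ± 0.443, Nrp1 at -4.00 ± 0.415, Eno3 at -3.18 ± 0.332, Capn3 at -2.99 ± 0.343, Fcer2 at -2.96 ± 0.619 and Pard3 at -2.71 ± 0.326. Qrfpr, Enpp1 and Pmp22 (3 treated values) were at least 9.92-fold, 7.38-fold and 6.94-fold lower. Between 4045 and 4487 probes were called when any 1 rat was left out.

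**Figure D2:**
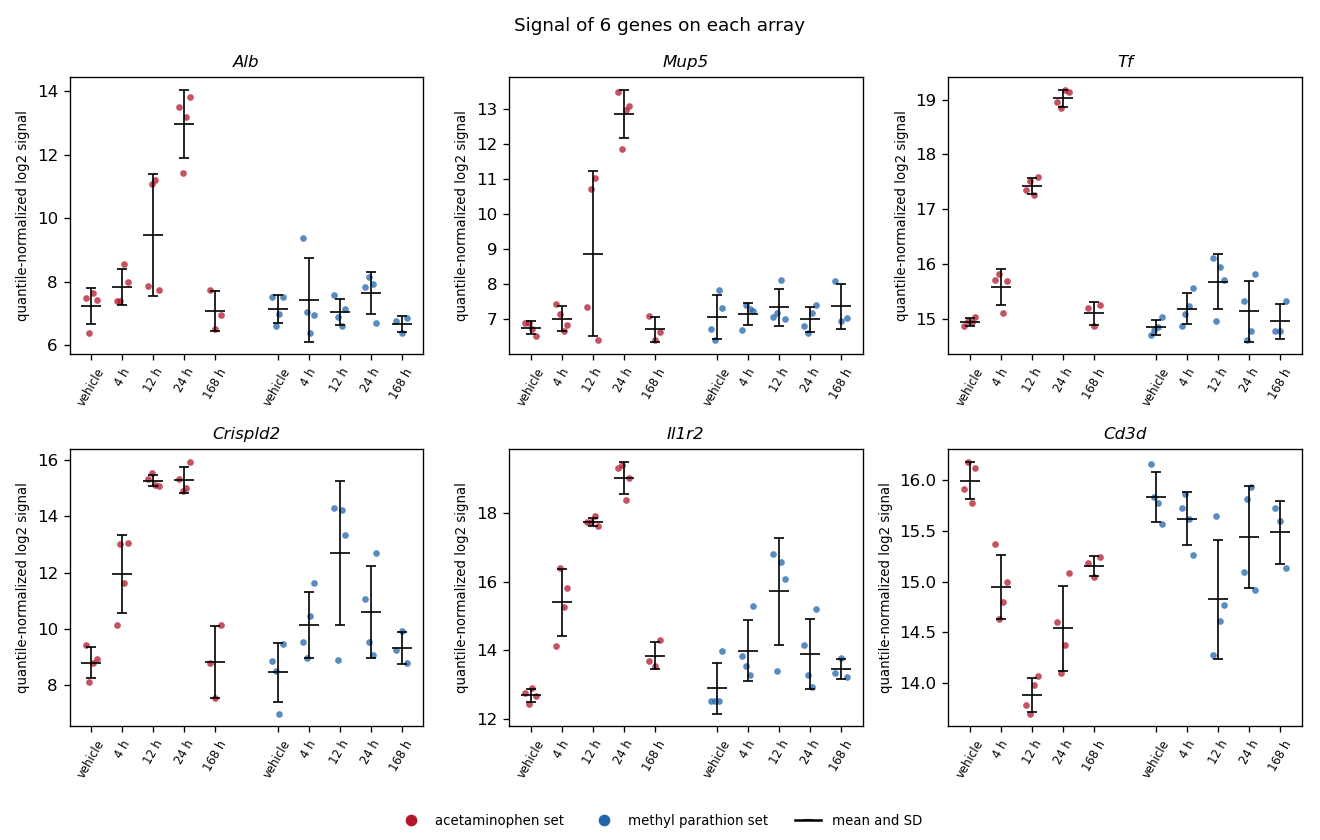
Quantile-normalized log2 signal (y axis) of Alb (probe 21581708), Mup5 (probe 21580420), Tf (probe 21575946), Crispld2 (probe 20706995), Il1r2 (probe 22027162) and Cd3d on each array, by group (x axis); points are arrays, bars the mean and SD. Alb and Mup5 were above background in 2 of 4 rats at 12 h and 4 of 4 at 24 h after acetaminophen.

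At 168 h after acetaminophen, the cell cycle list was higher and the T cell list lower (n = 3 and 4). The vehicle rats were killed at 24 h, so that age or handling cannot be told apart from the chemical here. Of the probes called, 455 were called in the same direction 168 h after methyl parathion, against 130 for independent lists. Cdc20, an activator of mitotic exit, rose by 1.26 ± 0.295, Birc5, survivin, by 1.16 ± 0.293 and Top2a, a topoisomerase of dividing cells, by 1.30 ± 0.384. Alox15, a lipoxygenase of eosinophils, rose by 2.25 ± 0.35 log2. Of 15 cell cycle genes 5 rose (6 adjusted over the list alone; mean 0.56, adjusted p = 0.00072, and adjusted p = 0.51 with an estimated correlation), and the score was above all vehicle rats in 2 of 3. Of 16 T cell markers 5 fell (10 adjusted over the list alone; mean -0.69, adjusted p = 0.000902, and adjusted p = 0.59 with an estimated correlation). Changes included Thy1 at -2.26 ± 0.444, above background in 1 of 3 treated rats, Cd247 at -1.06 ± 0.216 and Cd8a at -0.86 ± 0.185. Of 12 neutrophil markers 1 rose, Mmp9 by 1.08 ± 0.299 (2 adjusted over the list alone; adjusted p = 0.0278, and adjusted p = 0.7 with an estimated correlation). Of 9 eosinophil, basophil and mast cell genes 1 rose, Alox15 (1 adjusted over the list alone; adjusted p = 0.0443, and adjusted p = 0.41 with an estimated correlation), with the score above all vehicle rats in 2 of 3. Ribosomal protein genes fell in 10 of 37 cases (11 adjusted over the list alone; adjusted p = 0.0186, and adjusted p = 0.86 with an estimated correlation). Proteasome genes fell in 7 of 26 (9 adjusted over the list alone; adjusted p = 0.0429, and adjusted p = 0.81 with an estimated correlation). Rpl3 changed by -0.93 ± 0.171 and Psma2 by -0.93 ± 0.172. The fall was not particular to T cells. Scores of B cell, natural killer and monocyte markers, not called here, were also below all vehicle rats in 3 of 3 (means -0.539, -0.238 and -0.329).

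Of all probes 1421 differed at 168 h after acetaminophen (394 higher, 1027 lower; 440 named genes). Further rises were those of Cryaa at 1.80 ± 0.461, Or10d5 at 1.73 ± 0.385, Trim10 at 1.51 ± 0.463, Slk at 1.41 ± 0.424, Pxmp2 at 1.40 ± 0.437 and Nos1ap at 1.40 ± 0.424. Falls were those of Mat2a, which makes S-adenosylmethionine, at -2.29 ± 0.666 from 2 treated values, of which 1 was above background, Hfe at -2.25 ± 0.402 and Hspa14 at -2.13 ± 0.337. Nat2, an acetyltransferase, was at least 5.09-fold, Cx3cr1, the fractalkine receptor, at least 4.03-fold, and Adap1 at least 4.3-fold lower. With median centring 3.86% of called probes were higher in place of 27.7%, and the median change of the tested probes was -0.38 (-0.061 with quantile normalization). The count was 2875 with array weights, 2186 with brightness as a covariate, 390 without rat 2 of the 168 h group, 891 without vehicle rat 1 and 495 with the kit control ratio as a covariate, which was 0.401 log2 above the vehicle rats in this group. With that covariate the 1421 probes kept a median 90.8% of their change, and all their sign.

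At 4 h after methyl parathion no probe passed the limma test (n = 4 and 4; 0 of 12805, 1371 at an unadjusted p under 0.05 against 640 expected). Prg2, the eosinophil major basic protein, differed from the vehicle rats by 1.23 ± 0.523 log2 and Defa5, a defensin, by 1.30 ± 0.648, neither past the test. Granule protein genes of immature granulocytes shifted upward as a list (0 of 5 past the test, 0 adjusted over the list alone; mean 0.98, adjusted p = 0.0186, and adjusted p = 0.56 with an estimated correlation). T cell markers shifted downward (0 of 16, and 1 adjusted over the list alone; mean -0.31, adjusted p = 0.0122, and adjusted p = 0.7 with an estimated correlation), with the score below all vehicle rats in 3 of 4. Cell cycle genes shifted upward (0 of 15, and 0 adjusted over the list alone; mean 0.28, adjusted p = 0.0495, and adjusted p = 0.7 with an estimated correlation). With array weights 562 probes were called, and with all 8 vehicle rats 1.

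At 12 h after methyl parathion, T cell transcripts were lower and glucocorticoid-induced and neutrophil transcripts higher (n = 4 and 4). Crispld2 rose by 4.25 ± 0.835, Il1r2 by 2.83 ± 0.525 and Cebpd by 1.10 ± 0.25 log2. In rat 2 Crispld2 was at 8.88, within the 6.97 to 9.47 of the vehicle rats, against 13.34 to 14.29 in the other 3. Its neutrophil and T cell scores, 0.11 and -0.28 log2 from the vehicle mean, were also the nearest to it. Vehicle rat 4 stood apart in the neutrophil score, at 0.583 against -0.221 to -0.159 in the other vehicle rats. Ccr7, the homing receptor of naive T cells, changed by -1.54 ± 0.291, S1pr1, which guides lymphocytes out of lymph nodes, by -1.80 ± 0.336 and Cd8a by -1.05 ± 0.171. Of 16 T cell markers 11 fell (12 adjusted over the list alone; mean -0.93, adjusted p = 2.88e-08, and adjusted p = 0.41 with an estimated correlation). Of 15 glucocorticoid-induced genes 7 rose (8 adjusted over the list alone; mean 0.92, adjusted p = 1.85e-05, and adjusted p = 0.41 with an estimated correlation). Il1r2 is a member of this list and of the neutrophil list. Of 12 neutrophil markers 4 rose (6 rose and 1 fell adjusted over the list alone; mean 0.71, adjusted p = 0.000818, and adjusted p = 0.56 with an estimated correlation). Ribosomal protein genes fell in 4 of 37 cases (12 adjusted over the list alone; mean -0.28, adjusted p = 5.98e-06, and adjusted p = 0.59 with an estimated correlation). Inflammatory cytokine and NF-kB target genes rose in 4 of 19 (6 adjusted over the list alone; adjusted p = 0.0191, and adjusted p = 0.53 with an estimated correlation). Erythroid genes rose in 1 of 15, Gata1 by 1.08 ± 0.293 (1 adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.77 with an estimated correlation). The erythroid score lay beyond all vehicle rats in 2 of 4, and the neutrophil, glucocorticoid, NF-kB target and ribosomal scores in 3.

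Of all probes 1029 differed at 12 h after methyl parathion (399 higher, 630 lower; 355 named genes). Further rises were Clec10a at 2.12 ± 0.609, St14 at 1.99 ± 0.34, Ly6i at 1.83 ± 0.477, Gng8 at 1.73 ± 0.304, Usp2 at 1.66 ± 0.39, Bco1 at 1.51 ± 0.43 and Lmna, lamin A, at 1.46 ± 0.26. Falls were Dnase2b at -2.95 ± 0.609, Dpp4 at -1.79 ± 0.474, Sv2b at -1.70 ± 0.522 and Adgre4 at -1.70 ± 0.401. Il2ra, the interleukin 2 receptor alpha chain, Camk2d, Gabbr1 and Per3, a clock gene, were at least 3.87-fold, 3.79-fold, 3.75-fold and 3.48-fold lower. With median centring 20.1% of called probes were higher in place of 38.8%, and the median change of the tested probes was -0.25 (-0.077 with quantile normalization). The kit control ratio was 0.402 log2 above the vehicle rats. The count was 323 with median centring, 659 with no detection filter, 539 with brightness as a covariate, 3009 with all 8 vehicle rats and 4131 with array weights. It was 0 when limma saw only these 8 arrays, 268 with the kit control ratio as a covariate, 253, 487 and 374 without rats 1, 3 and 4 of the 12 h group, 1909 without rat 2, and 401 and 432 without vehicle rats 1 and 2. With the kit covariate the 1029 probes kept a median 90.9% of their change, and all their sign.

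At 24 h after methyl parathion (n = 4 and 4), Sgk1, a kinase induced by glucocorticoids, rose by 0.74 ± 0.179, Ddit3, a transcription factor of endoplasmic reticulum stress, by 0.72 ± 0.187, Stk40 by 0.82 ± 0.162 and Cybrd1, a ferric reductase, by 1.18 ± 0.28 log2. Cmklr1, the chemerin receptor, fell by 1.70 ± 0.333, Mag by 1.86 ± 0.456 and Fxyd4 by 2.14 ± 0.524. Of 15 glucocorticoid-induced genes 1 rose (1 adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.7 with an estimated correlation). T cell markers were lower as a list (0 of 16 past the test, 0 adjusted over the list alone; mean -0.38, adjusted p = 0.006, and adjusted p = 0.7 with an estimated correlation). Erythroid genes were higher as a list (0 of 15 past the test, and 2 adjusted over the list alone; mean 0.46, adjusted p = 0.00761, and adjusted p = 0.67 with an estimated correlation). Of 37 ribosomal protein genes 1 fell, Rpl39 by 0.53 ± 0.142 (1 adjusted over the list alone; mean -0.12, adjusted p = 0.00871, and adjusted p = 0.81 with an estimated correlation), and with median centring the list's direction relative to all other genes turned upward. The T cell, glucocorticoid and ribosomal scores lay beyond all vehicle rats in 2 of 4, and the erythroid score in 3.

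Of all probes 305 differed at 24 h after methyl parathion (93 higher, 212 lower; 58 named genes). Rises also held for Ubxn11 at 1.31 ± 0.35, Lmna at 0.96 ± 0.26, Slc35e4 at 0.94 ± 0.212 and Dgat1, an enzyme of triglyceride synthesis, at 0.87 ± 0.201. Falls held for Mdm4, a p53 inhibitor, at -1.55 ± 0.334, Add3 at -1.44 ± 0.384, Or5p78c at -1.29 ± 0.361, Clmp at -1.12 ± 0.293, Srsf5, a splicing factor, at -0.94 ± 0.255 and Tor2a at -0.89 ± 0.244. With median centring 2.28% of called probes were higher in place of 30.5%, and the median change of the tested probes was -0.29 (-0.059 with quantile normalization). The kit control ratio was 0.37 log2 above the vehicle rats. The count was 157 with no detection filter, 1104 with array weights, 0 when limma saw only these 8 arrays, 16 with the kit control ratio as a covariate, 30 and 17 without rats 3 and 4 of the 24 h group, 872 without rat 1, and 19, 59 and 183 without vehicle rats 1, 2 and 4. With the kit covariate the 305 probes kept a median 87.9% of their change, and all their sign.

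At 168 h after methyl parathion, cell cycle genes and the eosinophil gene Prg2 were higher (n = 3 and 4). Cdc20 rose by 1.39 ± 0.295, Stmn1, a microtubule regulator, by 0.97 ± 0.273, Tacc3, a spindle protein, by 0.71 ± 0.142 and Prg2 by 1.81 ± 0.565 log2. Prg2 is in the granule protein and the eosinophil list, neither called here. Their scores were above all vehicle rats in 3 of 3 (means 1.31 and 0.702). Chrna4, a nicotinic acetylcholine receptor subunit, was at least 6.64-fold lower. Of 15 cell cycle genes 5 rose (6 adjusted over the list alone; mean 0.60, adjusted p = 0.0101, and adjusted p = 0.59 with an estimated correlation). Of 34 oxidative phosphorylation genes 10 rose and 2 fell, also adjusted over the list alone (mean 0.17, adjusted p = 0.0443, and adjusted p = 0.81 with an estimated correlation). Changes included Ndufs7 at 0.71 ± 0.176 and Ndufv3 at 0.69 ± 0.157.

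Of all probes 2334 differed at 168 h after methyl parathion (1165 higher, 1169 lower; 668 named genes). Rises also held for Mxd3 at 2.02 ± 0.627, St14 at 1.64 ± 0.367, Nrxn2 at 1.62 ± 0.547 and Asb2 at 1.61 ± 0.426. Falls held for Il17re at -2.34 ± 0.483 and Gja4, a connexin, at -2.33 ± 0.511. Golph3, Car5a, Kcnmb1, Slc38a3 and Pax8 were at least 6.26-fold, 5.04-fold, 4.87-fold, 4.73-fold and 4.48-fold lower. With median centring 10.9% of called probes were higher in place of 49.9%, and the median change of the tested probes was -0.26 (-0.082 with quantile normalization). The kit control ratio was 0.568 log2 above the vehicle rats. The count was 1536 with median centring, 3557 with array weights, 1286 without rat 2 of the 168 h group and 594 with the kit control ratio as a covariate, with which the 2334 probes kept a median 86.1% of their change, and all their sign.

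**Figure D3:**
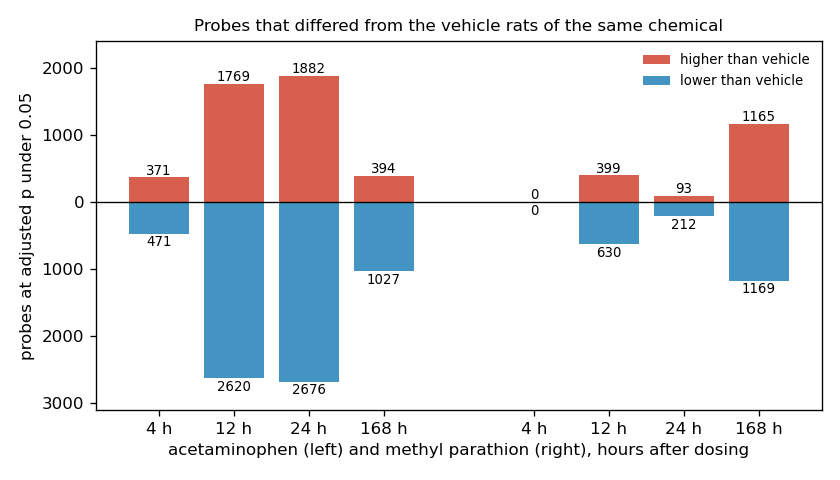
Number of probes past the limma test against the vehicle rats of the same chemical (y axis), higher above the line and lower below it, at each time (x axis). After acetaminophen 4389 probes differed at 12 h and 4558 at 24 h, and after methyl parathion 2334 at 168 h.

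The changes of the 2 chemicals were then compared with each other. At 24 h the lists below differed with the preset correlation, and none did with an estimated one. Hepatocyte genes differed in 8 of 21 cases (9 adjusted over the list alone; mean 1.92, adjusted p = 9.81e-05, and adjusted p = 0.38 with an estimated correlation). Natural killer genes differed in 15 of 17 (16 adjusted over the list alone; mean -1.58, adjusted p = 4.2e-09, and adjusted p = 0.39 with an estimated correlation). Neutrophil markers were higher after acetaminophen in 7 of 12 and lower in 1 (9 and 1 adjusted over the list alone; mean 1.95, adjusted p = 0.000471, and adjusted p = 0.47 with an estimated correlation). Inflammatory cytokine and NF-kB target genes were higher in 10 of 19 and lower in 3 (11 and 3 adjusted over the list alone; mean 1.85, adjusted p = 0.000838, and adjusted p = 0.38 with an estimated correlation). T cell markers were lower in 10 of 16, also adjusted over the list alone (mean -0.93, adjusted p = 0.00155, and adjusted p = 0.55 with an estimated correlation). B cell markers were lower in 5 of 6, also adjusted over the list alone (mean -1.63, adjusted p = 0.0345, and adjusted p = 0.55 with an estimated correlation). Rnase6 differed by -3.49 ± 0.626, Capn3 by -3.46 ± 0.486, Np4, a defensin, by -3.15 ± 0.952, Nrp1 by -3.12 ± 0.587 and Eno3 by -2.94 ± 0.47 (acetaminophen minus methyl parathion, log2). Car4, Cxcl2, Tgm1, Mup5, Mup4 and Alpl were higher after acetaminophen (adjusted p = 1.2e-09 to 2.7e-05), and none of the 6 was above background in an acetaminophen vehicle rat (3 usable values for Tgm1), so that no fold is given. In all 3290 probes differed at 24 h (1521 higher, 1769 lower), and 2028 with median centring. There 77.2% of called probes were higher in place of 46.2%, and the median difference of the tested probes was 0.24 (0.017 with quantile normalization).

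At 12 h Socs3 differed by 3.64 ± 0.573, Cxcr2 by 3.60 ± 0.649 and Gk by 3.48 ± 0.548 upward, and Tgm2 by -2.21 ± 0.426, St14 by -2.03 ± 0.48 and Mtfp1 by -1.87 ± 0.4 downward. Interferon-stimulated genes were higher after acetaminophen in 10 of 25 cases and lower in 1 (14 and 1 adjusted over the list alone; mean 0.88, adjusted p = 0.000305, and adjusted p = 0.55 with an estimated correlation). In all 1463 probes differed at 12 h (774 higher, 689 lower). The count was 966 without acetaminophen vehicle rat 4, 3462 with all 8 vehicle rats, 3166 with array weights, 908 with the kit control ratio as a covariate and 441 with median centring, and 5 of 100 deals of the rats between the chemicals, the real one included, gave as many. With median centring 96.6% of called probes were higher in place of 52.9%, with a median shift of 0.18 (0.012 with quantile normalization). At 168 h 435 differed (342 higher, 93 lower), with Sncg at 3.47 ± 0.881, Gja4 at 2.98 ± 0.722 and Thy1 at -2.52 ± 0.628. With median centring 97.1% of called probes were higher in place of 78.6%, with a median shift of -0.26 (-0.11 with quantile normalization). The count was 12 with all 8 vehicle rats, 175 with only the groups compared, 172 with median centring, 211 with no detection filter, 1030 with brightness as a covariate and 1565 with array weights. It was 0, 1, 2 and 7 without methyl parathion vehicle rat 4, acetaminophen vehicle rat 4, and rats 3 and 2 of the methyl parathion 168 h group, and 912 without its rat 1. It was 152 without acetaminophen vehicle rat 1, and 272, 142 and 144 without rats 1, 2 and 3 of the acetaminophen 168 h group. At 4 h no probe differed in limma (0, with 1879 at an unadjusted p under 0.05), nor between the vehicle groups (0, with 1378). Alternatives gave probes in both: at 4 h 229 with all 8 vehicle rats, 1111 with array weights and 350 without rat 1 of the acetaminophen group, and between the vehicle groups 105 with only these groups, 358 with brightness as a covariate, 1190 with array weights and 2 without acetaminophen vehicle rat 2.

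Probes called in the same direction after both chemicals numbered 305 higher (55.1 expected of independent lists) and 396 lower (129 expected) at 12 h, 29 higher (13.7 expected) and 42 lower (44.3 expected) at 24 h, and 165 higher (35.8 expected) and 290 lower (93.8 expected) at 168 h. Of the probes higher after methyl parathion 1, 12 and 0 were called lower after acetaminophen at 12, 24 and 168 h, and of those lower 7, 20 and 14 were called higher. Hmox1, heme oxygenase, rose by 1.46 ± 0.265 log2 (adjusted p = 3.2e-05) at 24 h after acetaminophen and changed by -0.80 ± 0.286 (adjusted p = 0.046) at 168 h after methyl parathion. The latter is -0.39 (adjusted p = 0.3) against all 8 vehicle rats, since the mean was 11.49 in this group, 12.29 in its vehicle rats and 11.46 in those of acetaminophen. Its other values, from -0.38 ± 0.265 at 4 h after methyl parathion to 0.51 ± 0.286 at 168 h after acetaminophen, did not pass. Ache, acetylcholinesterase, and Bche, butyrylcholinesterase, were above background in at most 2 arrays of a group and were not tested.

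The remaining 9 lists were not called in any comparison with vehicle, and the comparison with the smallest p is given for each. Of 11 monocyte markers 6 rose and 2 fell at 12 h after acetaminophen, also adjusted over the list alone (adjusted p = 0.255). At 24 h after acetaminophen, 10 of 29 apoptosis genes rose and 5 fell (11 and 6 adjusted over the list alone; adjusted p = 0.326), 3 of 12 aryl hydrocarbon receptor and xenobiotic metabolism genes rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.404), and 3 of 10 cholinergic genes fell, also adjusted over the list alone (adjusted p = 0.402). Of 9 p53 target genes 1 rose at 4 h after acetaminophen, also adjusted over the list alone (adjusted p = 0.407), and of 12 clock genes 0 changed at 168 h after acetaminophen, also adjusted over the list alone (mean 0.07, median -0.03, adjusted p = 0.623). At 12 h, 2 clock genes rose and 4 fell after acetaminophen (2 and 6 adjusted over the list alone; adjusted p = 0.781), and 1 rose and 2 fell after methyl parathion, also adjusted over the list alone (adjusted p = 0.653), where the score was below all vehicle rats in 4 of 4. After methyl parathion, 1 of 2 metallothionein and zinc transport genes rose at 12 h, also adjusted over the list alone (adjusted p = 0.123), and 1 of 9 brain genes fell at 24 h (1 fell and 1 rose adjusted over the list alone; adjusted p = 0.425). Of heart muscle genes 1 of 3 fell at 168 h, also adjusted over the list alone (adjusted p = 0.0889).

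**Figure D4:**
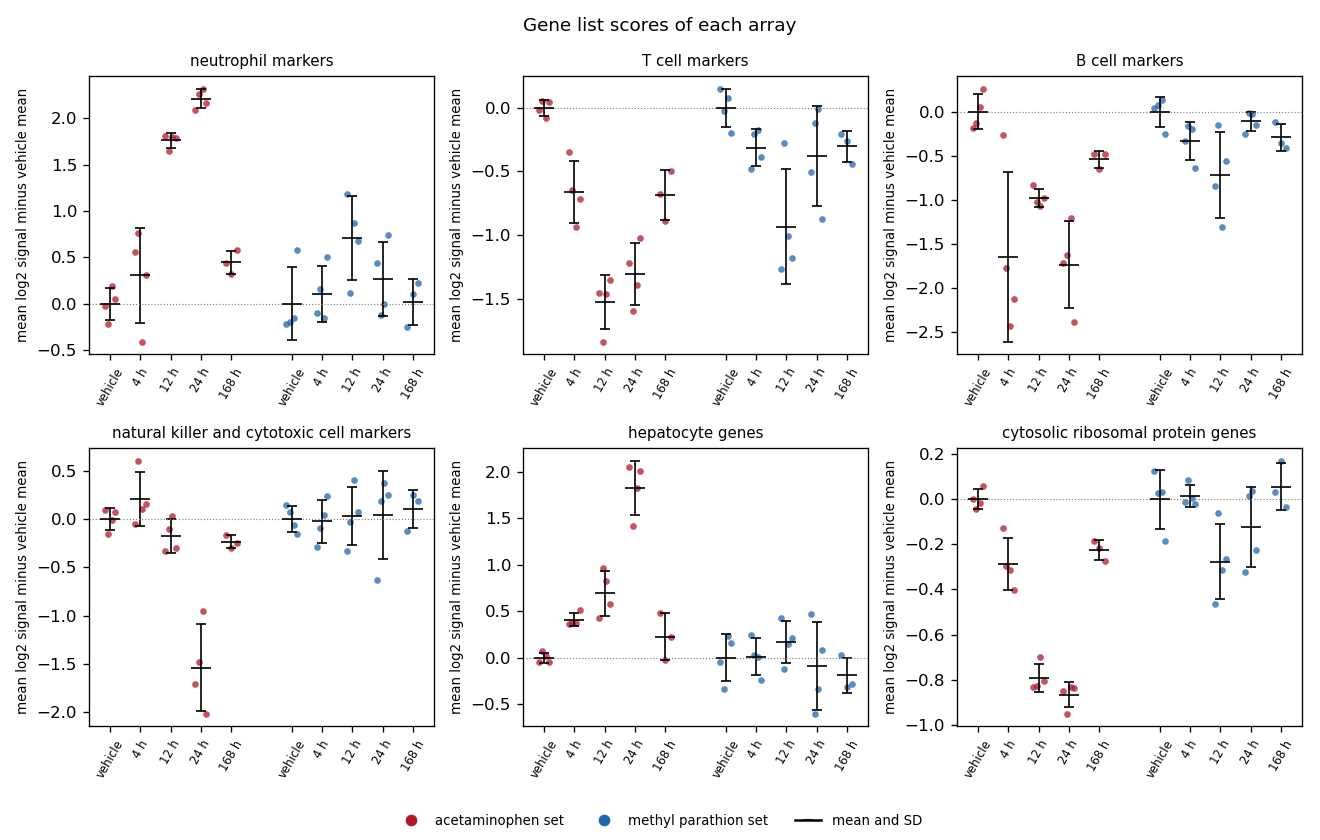
Mean log2 signal of the measured members of 6 gene lists minus the mean of the vehicle rats of the same chemical (y axis) on each array, by group (x axis); points are arrays, bars the mean and SD. The neutrophil mean is 2.21 at 24 h after acetaminophen and the T cell mean -0.93 at 12 h after methyl parathion.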

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

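The tests of the liver explanations, of time of day and of all lymphocytes, the fits with brightness or the kit control ratio as a covariate, the size of the changes kept, and the look at brightness in another split, were chosen only after the result was seen.

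Single arrays far from the other 3 of their group were sought in 40 array measures, 248 list scores and 984 sets of named gene values, and chance gives about 1 in 20. They were found in 1, 17 and 60. Rat 2 at 24 h after acetaminophen had 1.858% of spots with a failed flag, against 0.5622 to 0.7633% in the other 3. List scores are mean log2 signals minus the vehicle mean. For the acetaminophen rats, the scores apart were the erythroid score of rat 3 at 12 h (-0.0978) and rat 4 at 24 h (0.414), and the eosinophil, basophil and mast cell (0.16), NF-kB target (-0.0994) and endoplasmic reticulum stress scores (0.468) of rat 3 at 4 h. Others were the hepatocyte score of rat 4 at 4 h (0.514), the p53 score of vehicle rat 2 (-0.252), the endoplasmic reticulum stress score of rat 1 at 12 h (0.202) and the ribosomal protein score of rat 2 at 24 h (-0.95). For methyl parathion they were the neutrophil (0.583) and endoplasmic reticulum stress scores (0.0653) of vehicle rat 4 and the cholinergic score of vehicle rat 3 (0.124). In treated rats they were the glucocorticoid score of rat 4 at 4 h (0.704), the cell cycle score of rat 3 at 4 h (0.382), the immediate early score of rat 2 at 12 h (-0.128), the endoplasmic reticulum stress score of rat 1 at 12 h (0.364) and the p53 score of rat 2 at 24 h (0.405).

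The changes of the 2 chemicals differed from each other, by a test of the difference itself, in 1463 probes at 12 h, 3290 at 24 h and 435 at 168 h. Of whole lists 37 differed with the preset correlation and 0 with an estimated one. Means below are acetaminophen minus methyl parathion in log2, each followed by its adjusted p with the preset and with an estimated correlation. At 4 h they were -1.32 for B cell (0.00109, 0.39), -0.351 for T cell (0.0373, 0.64), 0.229 for natural killer (0.0324, 0.72) and 0.658 for erythroid genes (0.00205, 0.55). They were 1.01 for platelet (0.00109, 0.39), -0.661 for MHC class II (0.00296, 0.55), 0.735 for glucocorticoid-induced (0.000255, 0.44) and 0.284 for endoplasmic reticulum stress genes (0.0131, 0.54). They were -0.3 for ribosomal protein (1.99e-06, 0.55), -0.301 for oxidative phosphorylation (5.67e-06, 0.44) and -0.218 for proteasome genes (0.00249, 0.57). At 12 h they were 1.05 for neutrophil (0.0159, 0.57), -0.594 for T cell (0.00453, 0.57), 0.881 for interferon-stimulated (0.000305, 0.55), 0.92 for NF-kB target (0.0131, 0.44) and 0.643 for immediate early genes (0.0159, 0.44). They were 0.598 for hypoxia and glycolysis (0.00453, 0.47), -0.514 for ribosomal protein (2.78e-11, 0.39), -0.505 for oxidative phosphorylation (1.52e-09, 0.38) and -0.181 for proteasome genes (0.0335, 0.64). At 24 h they were 1.95 for neutrophil (0.000471, 0.47), -1.63 for B cell (0.0345, 0.55; 0.244 before gene matching was corrected), -0.929 for T cell (0.00155, 0.55), -1.58 for natural killer (4.2e-09, 0.39), 1.92 for hepatocyte (9.81e-05, 0.38) and 0.509 for Nrf2 genes (0.0373, 0.44). They were 1.11 for interferon-stimulated (0.000935, 0.57), 1.85 for NF-kB target (0.000838, 0.38), 0.917 for hypoxia and glycolysis (0.000401, 0.39), -0.743 for ribosomal protein (2.78e-11, 0.39) and -0.394 for oxidative phosphorylation genes (0.00109, 0.55). At 168 h they were 0.509 for erythroid (0.0217, 0.63), 0.419 for hepatocyte (0.0394, 0.55), 1.83 for heart muscle (0.00453, 0.29; 0.112 before gene matching was corrected), -0.29 for ribosomal protein (0.00296, 0.64), -0.301 for oxidative phosphorylation (0.00109, 0.55) and -0.34 for proteasome genes (0.00124, 0.55).

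Of 140 control spots, which no comparison used, 24 were higher than in the vehicle rats at 12 h and 29 at 24 h after acetaminophen, and 17 at 24 h and 22 at 168 h after methyl parathion. In the same order 10, 11, 26 and 36 were lower. Of the 30 spots of the labelling kit, 14 were called at 24 h and 19 at 168 h after methyl parathion.

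Splits of the same arrays into other groups were fitted to see whether chance could give as many probes. The real split counts as 1, the fewest possible, and each comparison was read alone, without adjustment over them. Only the real split gave as many probes at 12 h (1 of 35 splits, 4389 probes, highest other 259), 24 h (1 of 35, 4558, highest other 132) and 168 h (1 of 35, 1421, highest other 52) after acetaminophen. The same held at 168 h after methyl parathion (1 of 35, 2334, highest other 509). This goes against chance in each of these comparisons alone, but 35 splits without adjustment cannot exclude it. Another split gave as many at 4 h after acetaminophen (2 of 35, 842, highest other 862), and at 12 h (2 of 35, 1029, highest other 1176) and 24 h (2 of 35, 305, highest other 865) after methyl parathion. For the difference between the chemicals only the real deal gave as many at 24 h (1 of 100, 3290, highest other 2628), while 5 of 100 did at 12 h (1463, highest other 2763). At 168 h 2 of 100 splits gave as many (435, highest other 463), few enough by the rule set beforehand. But the count was 0 to 912 with 1 rat left out and 12 with all 8 vehicle rats, so that chance is not excluded. Where no probe was called every split gives as many, so that the splits decide nothing at 4 h after methyl parathion (35 of 35; 0, highest other 1), between the vehicle groups (35 of 35; 0, highest other 390) or for the difference at 4 h (100 of 100; 0, highest other 950). At 24 h after methyl parathion another split called several times the real count, 865 against 305, which points to a structure of the samples. It parts the brighter arrays, of rats 2 and 3 and vehicle rats 1 and 2 (raw medians 330.6 to 389.6), from the dimmer ones (219.7 to 265.9), and with brightness as a covariate the real groups gave 362 probes. The highest other splits at 4 h after acetaminophen and 12 h after methyl parathion differed from the real one by 1 exchanged pair, rat 1 for vehicle rat 2 and rat 2 for vehicle rat 4.

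Hepatocyte transcripts were higher in blood RNA 24 h after acetaminophen. RNA of liver cells in the collected blood may be the source: 95% of the 20 list members in no other list had a positive change and 14 rose, with Alb at a mean log2 signal of 12.97. Members did not all move alike. At 12 h Tf was at 17.26 to 17.58 in all 4 rats, while Alb was at 7.87 and 7.74 in rats 1 and 4 and at 11.08 and 11.21 in rats 2 and 3. Leukocytes were collected on a filter, and the order of the 4 rats by Alb and by the median of the other members was not alike (rho = 0.4), so that this stays open. A larger share of neutrophils is not excluded. From 12 to 24 h the 20 members gained a median 0.611 log2 more than the neutrophil markers. This gap is more than 2 of its SE over rats (0.25) but not over genes (0.342). Single neutrophil markers gained -1.55 to 1.75, and 10 of the 20 members were below background in at least 1 rat at 12 h. For the 9 members detected on every 12 and 24 h array the gap was 0.585 (SE 0.265 over rats and 0.323 over genes). Of these, 0 gained more than the largest gain of a neutrophil marker. Alb and 4 Mup genes, among the largest rises, gained a median 3.64, and their change at 12 h over that at 24 h was 0.658 (SE 0.29) of the same ratio of the neutrophil list, but 4 of these 5 were above background in 2 of 4 rats at 12 h, so that they exclude nothing.

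Neutrophil markers were higher and T cell markers lower at 12 h after both chemicals. A fall of all lymphocytes alike is argued against, since the T cell minus natural killer score was below every vehicle array in 8 of 8 arrays, but B cell scores, not called as lists, were lower too (mean -0.978, adjusted p = 0.185, and -0.717, adjusted p = 0.25, below all vehicle rats in 4 and 3 of 4), so that a fall of T and B cells together stays open. Array brightness as the whole cause of the 2 list shifts is argued against, since with it as a covariate the means of neutrophil and T cell markers were 1.82 and -1.42 after acetaminophen and 0.778 and -0.808 after methyl parathion (1.76, -1.53, 0.709 and -0.933 without it; largest adjusted p 0.00066 with the preset correlation, while with an estimated one, without the covariate, p was 0.41 and 0.56). For single probes at 12 h after methyl parathion it stays open: 539 were called in place of 1029, whose median change went from 0.848 to 0.789 log2 and median SE from 0.217 to 0.228. Time of day may apply at 12 h, since the vehicle rats were killed only at 24 h. After methyl parathion it cannot be told apart from an effect of the chemical, and the 24 h shift was at most 0.404 of the 12 h shift. Of 12 clock genes 2 rose and 4 fell after acetaminophen, and 1 rose and 2 fell after methyl parathion, at 12 h. After acetaminophen the 24 h shift, with the hour of killing matched, was at least 0.855 of the 12 h shift (means 2.21 and -1.31). It came from other rats and does not decide what moved the rats killed at 12 h. An hour effect alike in both chemicals would cancel in their difference at 12 h. This was 1.05 for neutrophil and -0.594 for T cell markers, called with the preset correlation and not with an estimated one. That difference argues against time of day as the whole cause after acetaminophen only with the preset correlation. Time of day as a part of the 12 h shift stays open.

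The 2334 probes called 168 h after methyl parathion were weighed against 3 explanations. Noise near the detection limit as the source of all calls is argued against, since 1685 of them were among the 6473 probes detected on all arrays. The share called among these was 1.43 times that among all (26 and 18.2%). This does not cover the calls of the other probes. On average 37.89% of probes were above background in this group, against 46.38% in its vehicle rats. A late difference shared by all rats killed at 168 h, such as age or handling, may apply: 455 probes were called in the same direction after both chemicals, against 130 for independent lists, and 64 against 11.1 with the kit control ratio as a covariate. With that covariate 594 probes were called, under the bound set before the count was seen, but the probes called without it kept a median 86.1% of their change, and all 2334 their sign. Over these probes the median change went from 0.901 to 0.761 log2 and the median SE from 0.235 to 0.261. The count thus mixes smaller changes with larger errors and does not decide alone. The ratio is taken against the median gene probe, and on nearly all arrays most gene probes were below background (36.41 to 51.7% above it). It is therefore no direct measure of the labelled RNA, and a difference in the amount of labelled RNA stays open.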

How the results depend on the processing

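Array brightness and the kit control ratio as covariates were chosen only after the result was seen, and all other alternatives before. All 13 counts of probes stayed within 1.5 times their value with the authors' series table, only probes detected on all 38 arrays, a floor at the 25th percentile, flagged spots kept, a variance prior without trend and a replicate block. In the order 4, 12, 24 and 168 h after acetaminophen, then after methyl parathion, then the differences, the replicate block gave 821, 4356, 4543, 1604, 0, 1046, 315, 2420, 0, 1442, 3269 and 398 probes. Counts that moved are given here, with AP for acetaminophen and MP for methyl parathion. Median centring gave 201 at AP 4 h, 323 at MP 12 h, 1536 at MP 168 h, and differences of 441 at 12 h, 2028 at 24 h and 172 at 168 h. No detection filter gave 540 at AP 4 h, 659 at MP 12 h, 157 at MP 24 h and a difference of 211 at 168 h. All 8 vehicle rats gave 1 at MP 4 h, 3009 at MP 12 h, and differences of 229 at 4 h, 3462 at 12 h and 12 at 168 h, and cannot apply to the vehicle groups. Array weights gave 2365 at AP 4 h, 2875 at AP 168 h, 562 at MP 4 h, 4131 at MP 12 h, 1104 at MP 24 h, 3557 at MP 168 h, differences of 1111 at 4 h, 3166 at 12 h and 1565 at 168 h, and 1190 between vehicle groups. Only the groups compared gave 0 at AP 4 h, MP 12 h and MP 24 h, a difference of 175 at 168 h and 105 between vehicle groups. Calls of at least 2-fold, which are fewer by construction, were 392, 2083, 2316 and 592 after AP, 387, 175 and 992 at 12, 24 and 168 h after MP, and 742 and 2168 for the differences at 12 and 24 h. Brightness gave 2186 at AP 168 h, 539 at MP 12 h, a difference of 1030 at 168 h and 358 between vehicle groups. The kit control ratio gave 495 at AP 168 h, 268 at MP 12 h, 16 at MP 24 h, 594 at MP 168 h and a difference of 908 at 12 h, and the probes called without it kept a median 90.8, 90.9, 87.9, 86.1 and 96.4% of their change. Leaving out 1 rat gave 179 to 1624, 3806 to 4213, 4045 to 4487 and 390 to 1243 after AP, and 0 to 0, 253 to 1909, 17 to 872 and 1286 to 2035 after MP. For the differences it gave 0 to 350, 966 to 1833, 2777 to 4064 and 0 to 912, and 0 to 2 between vehicle groups. Of 58 called lists 58 were not called with an estimated correlation, and camera's direction for the ribosomal protein list at MP 24 h, relative to all other genes, turned upward with median centring, while its mean stayed negative (-0.128). Lists also lost their call: 17 with probes detected on all arrays, 9 with brightness, 7 with median centring, 5 without the trend, 4 each with no filter, all 8 vehicle rats, array weights and the kit control ratio, 3 with the replicate block, 2 with the series table, 1 with only the groups compared, and 53 times with 1 rat left out. Of 450 gene values calls were lost in 131 with only the groups compared, 85 with median centring, 74 with the kit control ratio, 51 with no filter, 27 with all 8 vehicle rats, 24 without the trend, 23 with brightness, 7 with the replicate block, 5 with array weights, 2 each with the series table and the floor, 1 with flagged spots kept, and 574 times with 1 rat left out. Calls were gained in 38 with array weights, 16 with all 8 vehicle rats, 14 with probes detected on all arrays, 6 with brightness, 5 with only the groups compared, 4 with the replicate block, 2 with the floor, 1 each with the series table and the kit control ratio, and 27 times with 1 rat left out. The following changed sign, none of them past the test before or after. With all 8 vehicle rats they were Hmox1 at AP 4 h (-0.0705), AP 12 h (-0.1925), MP 4 h (0.03292) and MP 24 h (0.1542), Gata2 at AP 168 h (0.1907), Itih3 at AP 24 h (0.1492) and Birc5 at MP 4 h (0.1961). With median centring they were Rps15 at AP 168 h (-0.1162), Gata3 at AP 4 h (-0.07588), Hmox1 at MP 12 h (-0.08102) and Zap70 at MP 24 h (-0.145). With array weights they were Rhob at AP 4 h (0.07776) and Birc5 at MP 4 h (0.1029), with brightness Hmox1 at AP 12 h (-0.1102) and MP 12 h (-0.2367), and with the kit control ratio Gata3 at AP 4 h (-0.01512). Leaving out 1 rat gave ranges that crossed 0 for Gata2 at AP 168 h (-0.8044 to 0.3095), Itih3 at AP 24 h (-0.3334 to 0.2997), Gata3 (-0.1154 to 0.1779), Rhob (-0.1316 to 0.1123) and Slc4a1 (-0.6379 to 0.2199) at AP 4 h and Ctla4 at MP 12 h (-0.1295 to 0.4614). So did those of Hmox1 at MP 12 h (-0.01933 to 0.3754) and MP 24 h (-0.5307 to 0.02901), Zap70 at MP 24 h (-0.02285 to 0.3232) and Birc5 at MP 4 h (-0.3728 to 0.05427). Beyond the limit of 2-fold, which lowers counts by construction, the cause was not tested. A correction of foreground and background and a batch of slides or scans were planned and not run, since the files give neither. Signal over background limited what was tested, with 36.41 to 51.7% of probes above it per array.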
